A study of Mus musculus with 52 samples.

How the data were processed

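Total RNA from the liver of C57Bl6/N mice labelled male was hybridized to 52 Affymetrix Mouse Genome 430 2.0 arrays, 1 per sample, per the labels' protocols. RNA was isolated with TRIzol, copied into cDNA and transcribed into biotin-labelled cRNA with oligo dT primers, per the labels' protocols. The deposited values were log2 probe set summaries made with oligo 1.52.0 and RMA, per the submitters' processing notes. RMA corrects background, equalizes the distributions of arrays and summarises the probes of a set, which hides a shift shared by most genes. Whether all 52 arrays were normalized together is not given in the sources used here, and scan dates and scanner files were not used here. The groups and replicate numbers came from the sample titles. The number of arrays, and not a read depth, limits the precision.

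The table held 45101 probe sets, of which 34958 had 1 gene in the platform annotation, 932 had several and 9211 were not listed there. Control probe sets numbered 64. Probe sets with several genes or none were not named. Genes were matched through their Entrez identifiers to a gene table of the GRCm38.p6 assembly, which held 18033 of the 18194 genes, and 161 kept the annotation symbol. A gene with more than 1 probe set, as 9012 had, was represented by the probe set with the highest mean over all arrays. Where probe sets of a gene were called in both directions, another set can give the other direction, as for 47 of 1656 genes at 1 hour and 755 of 8846 at 1 week.

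Each time after the operation was compared with the 5 controls, and 5 further contrasts compared times with each other. All 52 arrays entered one limma 3.58.1 fit of group means (lmFit and eBayes, in R 4.3.3), because most groups hold few arrays. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes of a contrast, and a gene was called at an adjusted p under 0.05. A moderated F test over the 11 contrasts with control gave the genes changed at any time. All comparisons with control share the same 5 arrays, so no overlap or correlation between them was computed.

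Lists of 30 pathways and 11 cell types, 41 in all, were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over 451 tests for the times against control and over 205 for the contrasts between times. For the times against control 114 calls were made, and 0 remained with a correlation estimated from the residuals, while fry called 109. For the contrasts between times 78 calls were made, 2 remained with an estimated correlation, and fry called 21. Member counts were also adjusted over the list alone. After list results had been seen, 3 members that had been matched through old synonyms, which are now the names of other genes, were taken out of their lists and the tests were run again.

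The groups, lists, main tests and 16 alternatives were chosen before the data were examined, and the added alternatives, tests of explanations and other splits of the arrays after. Genes were named by a fixed rule. It took 20 index genes, of which 19 were measured, up to 6 highest and 6 lowest called genes per comparison with complete separation of the 2 groups, and up to 4 called members with the largest change per list, with the largest in the rarer direction. Among the genes the rule gave, those named were chosen after their values were seen, for stability when single arrays were left out and for a known function. The 16 alternatives were a replicate block, a fit of the 2 groups alone, the mean of a gene's probe sets, every probe set, a filter on genes below the 40th percentile of the highest group mean, median centring, a further quantile normalization, a trended and robust prior, array weights, an adjusted p under 0.01, a change of at least 2-fold, 3 subsets of the 24-hour arrays, camera with an estimated correlation and fry, and each array was also left out in turn for genes. The 7 added alternatives, chosen after seeing the data, used as a covariate the mean of the hybridization controls, of the poly-A controls or the Gapdh 3' minus 5' difference, or left out the 3 arrays with Xist signal, 7 doubted arrays, the 24-hour replicates 2 and 5 that correlate best with the 48-hour group or, for list tests, each array in turn. Arrays were doubted with Xist above 6, a Gapdh difference above 2 or a correlation with the rest of their own group below 0 over the 2000 most variable genes. These limits were set after the values were seen. The correlation limit was first 0.2, which named 12 arrays, and the version with 12 arrays was not run. The 7 were 24-hour replicates 1, 9, 10 and 11, control replicate 1, 1-week replicate 4 and 4-week replicate 1.

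Simulated data of 18194 genes tested the procedure. Of 50 genes changed 2-fold, 92% were found at 1 hour, 98% at 24 hours, 70% at 2 weeks and 80% for 3 months against 1 week. A shifted list was found in 16 of 16 simulations, with 2 others called in all. This does not vouch for calls that an estimated correlation ended. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.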

Results

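Gene expression was followed in the liver of C57Bl6/N mice labelled male after partial hepatectomy, an operation that removes most of the liver and after which the remnant regrows. Total RNA was hybridized to arrays on which each gene is read by 1 or more sets of short probes. The 52 arrays comprised 5 from untreated control mice and 47 from mice at 11 times after the operation. The operated groups held 3 arrays at 1 hour, 4 at 6 hours, 4 at 12 hours, 11 at 24 hours, 4 at 48 hours, 4 at 3 days, 4 at 4 days, 4 at 1 week, 2 at 2 weeks, 4 at 4 weeks and 3 at 3 months. No sham-operated livers were analysed here, so a difference from the controls holds the operation, the loss of tissue and any time-of-day effect. The labels do not state that the arrays of a group came from separate mice, so p-values measure the spread between these samples. Values are log2 expression, changes are log2 fold changes ± SE, and 18194 genes were tested in each comparison. Group means close to the median of all probe sets, 4.04 in the controls, are not separated from background, so folds against them are given as at least.

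The control arrays differed from the others in technical measures as well. The hybridization control transcripts, added to every sample in fixed amounts, averaged 10.85 ± 0.29 (SD, n = 5) in the controls, and the means of the operated groups lay between 9.73 and 10.38. The difference between the 3' and 5' probe sets of Gapdh, which grows as RNA degrades, averaged 1.61 ± 0.57 (SD, n = 5) in the controls, against group means between 0.65 and 1.10 elsewhere. The poly-A controls, added before labelling, averaged 6.88 ± 0.43 (SD, n = 5) in the controls and 4.89 ± 0.19 (SD, n = 4) at 4 days, the lowest group mean. Replicates 9, 10 and 11 of the 24-hour group had Xist, the RNA of the inactive X chromosome of females, between 9.12 and 9.48, whereas the other 49 arrays had it between 2.51 and 3.81. Over the 2000 most variable genes 4-week replicate 1 correlated at 0.941 with the 12-hour mean and at -0.50 with its own group. The 1-week replicate 4 had 0.38 and -0.28. Another group was closer than their own for 17 arrays, among them all at 1 and 4 weeks.

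In all, 11752 of the 18194 genes (64.6%) differed from the controls at one time or more. The counts given for each time depend on the number of arrays and share the same 5 controls, so they do not rank the times. For each list fixed before the data were examined, member counts are given with the camera test of the list against all other genes. For lists named more briefly, the parenthesis gives the members up and down over all genes and, marked alone, those adjusted over the list alone. Alternatives are other settings of the analysis, given with their values in the closing part, and not every called list is named.

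**Figure D1:**
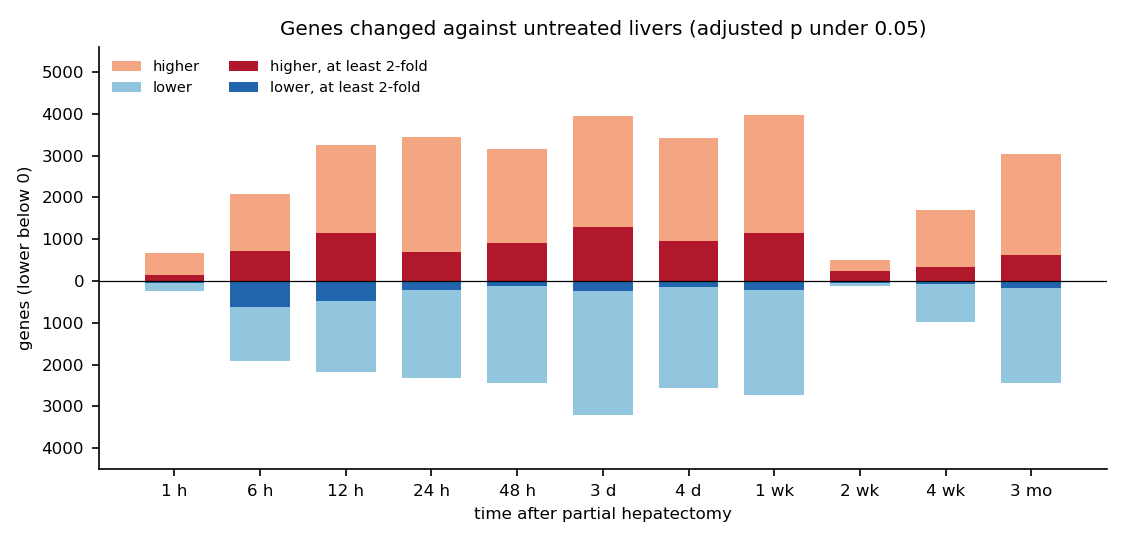
Genes that rose (above 0) and fell (below 0) at each of the 11 times against the 5 control arrays, with the genes changed at least 2-fold in the darker shade. The count was 917 at 1 hour, 7168 at 3 days, 620 at 2 weeks, where 2 arrays were measured, and 5476 at 3 months.

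One hour after the operation, the transcription factors Atf3 and Maff were higher than in untreated liver. Atf3 (2.77 ± 0.43) rose to 7.65 ± 0.70 (SD, n = 3) against 4.88 ± 0.46 (SD, n = 5) in the controls. The metallothioneins Mt2 (4.44 ± 0.54) and Mt1 (3.79 ± 0.48), which bind zinc and copper, were 21.7-fold and 13.9-fold above the controls. Maff (1.84 ± 0.32) rose as well. The long noncoding RNA Neat1 (-2.82 ± 0.57), the scaffold of paraspeckles, fell. In all 917 genes changed, 668 up and 249 down, 198 of them by at least 2-fold. Among the immediate early genes, 7 of 24 rose, 0 fell and 17 did not pass (13 and 0 adjusted over the list alone, adjusted p = 3.4e-08, or 0.89 with an estimated correlation). The index gene Egr1 stood at 1.09 ± 0.63 and Myc at 1.44 ± 0.54, and neither passed, though Myc did with array weights (1.69, adjusted p = 0.0079) and without the doubted arrays (1.73, adjusted p = 0.043). Of the Kupffer cell markers, genes of the resident macrophages of the liver, 5 of 15 rose, 0 fell and 10 did not pass (9 and 0 adjusted over the list alone, adjusted p = 1.3e-07, or 0.89 with an estimated correlation). Vsig4 (2.56 ± 0.58), a complement receptor, and C1qb (2.40 ± 0.53), a complement component, rose, and the hybridization controls of the 1-hour arrays averaged 10.30 ± 0.24 (SD, n = 3). At 1 hour the list test also called upward acute phase proteins (3 up and 0 down of 24, 3 and 0 alone), at adjusted p = 3.3e-05, or 0.89 with an estimated correlation. Rises in immediate early genes numbered 4 without 1-hour replicate 2 or control replicate 1 and 2 without 1-hour replicate 1. Rises in Kupffer cell markers numbered 3 without 1-hour replicate 1, 2 without control replicate 1 and 0 without 1-hour replicate 2. Rises in acute phase proteins numbered 5 without control replicate 2. The list call of acute phase proteins ended without 1-hour replicate 2 (adjusted p = 0.18), with adjusted p from 5.7e-10 to 0.18 over the alternatives at the preset correlation. Replicate 2 had Saa1 at 13.51, and the other arrays of the group at 8.82 and 9.24. Of the genes changed 72.8% rose, 83.2% after median centring and 47.6% after quantile normalization. A fit with the hybridization controls as a covariate gave 16 genes, and the calls of Neat1, Vsig4 and C1qb ended, while 376 passed with the poly-A controls and 237 with the Gapdh difference. Calls that the hybridization covariate ended, 3 here, kept 73.1% (Neat1, -2.06 ± 0.62) to 99.6% of their change (median 85.7%), with 1.15 times the error. Leaving out 1 array gave 269 genes without replicate 1, 373 without replicate 2, 473 without replicate 3 and 334 without control replicate 1. Without 1-hour replicate 2 the calls of Vsig4 (2.12) and C1qb (2.05) ended.

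At 6 hours 19 of 24 acute phase genes were higher, and 10 of 19 genes of cholesterol synthesis and 8 of 19 of fatty acid synthesis were lower. Lcn2 (8.52 ± 1.02), an iron-scavenging protein secreted in inflammation, reached 12.58 ± 0.03 (SD, n = 4) against 4.05 ± 1.40 (SD, n = 5) in the controls, a difference of at least 368-fold. Cyp7a1 (-6.10 ± 1.04), the rate-limiting enzyme of bile acid synthesis, was at least 68.5-fold lower. Cdkn1a (4.90 ± 0.58), an inhibitor of the cell cycle, rose, while the proliferation marker Mki67 stood at 0.14 ± 0.76 and did not pass. Changes were seen in 3999 genes, 2082 up and 1917 down, and 1327 changed at least 2-fold. The highest rises included Mt2 (6.64 ± 0.50), Saa2 (6.24 ± 1.06), Mt1 (5.74 ± 0.44), Rab30 (5.23 ± 0.55) and Saa1 (5.13 ± 0.84), and the deepest falls Hsd3b5 (-4.78 ± 1.25), Arrdc3 (-4.34 ± 0.57), Tmem25 (-4.25 ± 0.55) and Angptl8 (-3.86 ± 0.67). Among acute phase proteins, 19 of 24 rose, 0 fell and 5 did not pass (19 and 0 adjusted over the list alone, adjusted p = 4.6e-14, or 0.89 with an estimated correlation). Immediate early genes went both ways, and 12 of 24 rose, 2 fell and 10 did not pass (12 and 2 adjusted over the list alone, adjusted p = 0.00012, or 0.89 with an estimated correlation). Socs3 (3.83 ± 0.55), a feedback inhibitor of cytokine signalling, Ier3 (3.70 ± 0.71), Btg2 (3.24 ± 0.55) and Klf6 (2.67 ± 0.42) rose, whereas Dusp1 (-1.37 ± 0.37), a phosphatase of MAP kinases, fell. In cholesterol synthesis, 1 of 19 rose, 10 fell and 8 did not pass (1 and 11 adjusted over the list alone, adjusted p = 3.8e-05, or 0.89 with an estimated correlation), among them Insig1 (-2.89 ± 0.38), Mvd (-2.47 ± 0.33), Hmgcs1 (-2.39 ± 0.34) and Fdft1 (-2.22 ± 0.34). In fatty acid synthesis, 0 of 19 rose, 8 fell and 11 did not pass (0 and 10 adjusted over the list alone, adjusted p = 0.00016, or 0.89 with an estimated correlation), including Srebf1 (-3.02 ± 0.51), Fasn (-2.38 ± 0.53) and Mlxipl (-2.17 ± 0.35). Fatty acid oxidation and PPARa targets went the other way, and 11 of 24 rose, 0 fell and 13 did not pass (12 and 1 adjusted over the list alone, adjusted p = 0.00072, or 0.89 with an estimated correlation). Pdk4 (4.60 ± 0.86), which restrains pyruvate oxidation, Angptl4 (2.19 ± 0.41), an inhibitor of lipoprotein lipase, and Plin2 (2.05 ± 0.29), a lipid droplet protein, rose. At 6 hours the list test also called upward ribosome biogenesis (8 up and 0 down of 24, 12 and 1 alone) and unfolded protein response (9 up and 0 down of 20, 11 and 0 alone), at adjusted p = 0.00037 to 0.00082, or 0.89 with an estimated correlation. It called downward hepatocyte transcription factors (2 up and 8 down of 17, 2 and 11 alone), at adjusted p = 0.0045, or 0.89 with an estimated correlation. More genes fell than rose with array weights (3162 up and 3526 down), in a fit of these groups alone (2721 and 3011), without the doubted arrays (2107 and 2231) and with the hybridization covariate (1210 and 2074).

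At 12 hours genes of ribosome production and of the proteasome were higher, and 12 of 19 genes of fatty acid synthesis were lower. Lcn2 (8.64 ± 1.02) reached 12.69 ± 0.07 (SD, n = 4) against 4.05 ± 1.40 (SD, n = 5) in the controls. Nop58 (2.06 ± 0.34) and Rrp12 (1.94 ± 0.30), both needed to process ribosomal RNA, rose. Acss2 (-3.77 ± 0.63), which makes acetyl-CoA, and Thrsp (-3.48 ± 0.98), a regulator of lipogenesis, fell. Hsd3b5 (-6.90 ± 1.25), a steroid dehydrogenase of male liver, was at least 119-fold lower. The comparison called 5445 genes, 3257 up and 2188 down, 1634 of them by at least 2-fold. Further strong changes were Saa2 (6.36 ± 1.06) and Bmper (5.17 ± 0.76) upward and Upp2 (-5.22 ± 1.09), Hsd3b2 (-4.98 ± 0.79) and Coq8a (-4.47 ± 0.41) downward. In ribosome biogenesis, 19 of 24 rose, 0 fell and 5 did not pass (21 and 0 adjusted over the list alone, adjusted p = 1.4e-08, or 0.89 with an estimated correlation), Ddx21 (1.56 ± 0.26) among them. Of the proteasome subunits, 19 of 25 rose, 1 fell and 5 did not pass (19 and 1 adjusted over the list alone, adjusted p = 2.2e-05, or 0.89 with an estimated correlation). Psmc1 (1.01 ± 0.17) rose, and Psmb3 (-0.65 ± 0.14) fell. In fatty acid synthesis, 0 of 19 rose, 12 fell and 7 did not pass (0 and 13 adjusted over the list alone, adjusted p = 5.4e-07, or 0.89 with an estimated correlation), Srebf1 (-2.93 ± 0.51) included. At 12 hours the list test also called upward acute phase proteins (20 up and 0 down of 24, 20 and 0 alone) and fatty acid oxidation and PPARa targets (12 up and 1 down of 24, 14 and 1 alone), at adjusted p = 8.6e-14 to 4.7e-05, or 0.89 with an estimated correlation. It called downward plasma proteins of hepatocytes (2 up and 11 down of 25, 2 and 13 alone), cholesterol synthesis (0 up and 10 down of 19, 0 and 11 alone), cytochrome P450 drug metabolism (2 up and 7 down of 18, 2 and 8 alone) and bile acid synthesis and transport (1 up and 9 down of 21, 1 and 9 alone), at adjusted p = 0.00021 to 0.0087, or 0.89 with an estimated correlation. Falls in cytochrome P450 drug metabolism genes numbered 13 without the doubted arrays. Of the genes changed 59.8% rose, 72.2% after median centring and 49.9% after quantile normalization.

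At 24 hours macrophage and proteasome genes and 16 of 31 replication genes were higher, and male-biased genes were lower. Marco (3.23 ± 0.43), a scavenger receptor of macrophages, was at least 9.39-fold above the controls on its brightest probe set. It stood at 1.85 with the mean of its probe sets. Mcm6 (2.66 ± 0.59), a part of the replicative helicase, and Ccnd1 (2.76 ± 0.48), the cyclin of entry into the cycle, rose, while Mki67 stood at 1.07 ± 0.61 and did not pass, though it did with array weights (1.48, adjusted p = 0.011). Replicates 2 and 5 had Mcm6 at 9.74 and 9.25 and Mki67 at 7.77 and 6.84, while in the other 9 arrays Mcm6 lay between 5.09 and 8.54 and Mki67 between 2.95 and 5.69. They correlated at 0.57 and 0.55 with the 48-hour group and at 0.20 and 0.20 with their own. Without both, 9 replication genes rose and 3 fell. Afp (3.82 ± 0.39), a protein of fetal liver, rose at least 14.1-fold on its brightest probe set. It stood at 1.53 with the mean of its probe sets. With 11 arrays in the group, 5776 genes changed, 3447 up and 2329 down, 910 of them by at least 2-fold. Among the highest were Lcn2 (8.85 ± 0.82), Saa2 (6.38 ± 0.85) and Orm2 (5.08 ± 0.62). Among the lowest were Hsd3b5 (-4.76 ± 1.00), Inmt (-3.89 ± 0.74), Mup10 (-3.82 ± 0.58) and Gsta2 (-3.73 ± 0.38). Of the acute phase proteins, 21 of 24 rose, 1 fell and 2 did not pass (22 and 1 adjusted over the list alone, adjusted p = 1.5e-16, or 0.89 with an estimated correlation), and Hamp (-1.62 ± 0.43), the hormone that limits iron release, fell. For Kupffer cell markers, 12 of 15 rose, 0 fell and 3 did not pass (12 and 0 adjusted over the list alone, adjusted p = 2.3e-06, or 0.89 with an estimated correlation), with Vsig4 (2.61 ± 0.43), Cd163 (2.17 ± 0.39) and C1qb (2.11 ± 0.39) up. For the unfolded protein response, 11 of 20 rose, 0 fell and 9 did not pass (11 and 0 adjusted over the list alone, adjusted p = 9.7e-05, or 0.89 with an estimated correlation), with Sdf2l1 (2.33 ± 0.32) and Dnajc3 (1.59 ± 0.19) up. Among male-biased liver genes, 0 of 14 rose, 12 fell and 2 did not pass (0 and 12 adjusted over the list alone, adjusted p = 1.7e-05, or 0.89 with an estimated correlation), with Slco1a1 (-2.12 ± 0.60) down. Without the 3 arrays with Xist signal, 9 of these genes fell, and without all 7 doubted arrays 9. Of the cytochrome P450 genes of drug metabolism, 2 of 18 rose, 14 fell and 2 did not pass (2 and 14 adjusted over the list alone, adjusted p = 3e-04, or 0.89 with an estimated correlation). Cyp2c37 (-1.93 ± 0.45) fell, whereas Cyp2b10 (3.10 ± 0.60) rose. At 24 hours the list test also called upward proteasome subunits (19 up and 1 down of 25, 21 and 1 alone), ribosome biogenesis (15 up and 0 down of 24, 19 and 0 alone) and DNA replication and G1/S (16 up and 1 down of 31, 22 and 1 alone), at adjusted p = 3.2e-09 to 0.00068, or 0.89 to 0.96 with an estimated correlation. It called downward fatty acid synthesis (0 up and 14 down of 19, 0 and 16 alone), at adjusted p = 1.2e-06, or 0.89 with an estimated correlation. The call of DNA replication and G1/S ended under at least 1 alternative. Rises in DNA replication and G1/S genes numbered 9 without control replicate 3. The share of called genes that rose was 59.7%, 74.1% after median centring and 46.8% after quantile normalization. With the hybridization controls as a covariate, 2424 genes passed, and the calls of Mcm6 and Hamp ended, and replicates 5 and 6 alone gave 773. The 2 named calls ended by the hybridization covariate kept 45.8% (Mcm6, 1.22 ± 0.66) to 58.9% of their change (median 52.3%), with 1.15 times the error. Without the doubted arrays Cyp2c37 stood at -1.08, Hamp at -2.52, Hsd3b5 at -2.96 and Slco1a1 at -1.17, and without the arrays with Xist signal Slco1a1 stood at -1.35. Calls ended for Hamp with the Gapdh difference, for Hamp in a fit of these groups alone and for Hsd3b5 (-2.39), Mup10, Slco1a1 (-1.11), Cyp2c37 (-1.05) and Cyp2b10 with 24-hour replicates 5 and 6 only.

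At 48 hours the genes of DNA replication and of mitosis were far above the controls. Mki67 (5.83 ± 0.76) rose to 9.17 ± 1.09 (SD, n = 4) against 3.34 ± 0.19 (SD, n = 5) in the controls. Birc5 (5.74 ± 0.72), a part of the complex that guides chromosome segregation, Cdc20 (5.64 ± 0.82), an activator of the anaphase-promoting complex, and Ube2c (5.33 ± 0.71), its ubiquitin-conjugating enzyme, rose with it. So did the helicase subunits Mcm6 (5.01 ± 0.74) and Mcm5 (4.93 ± 0.75), Rrm2 (4.77 ± 0.81), which supplies deoxynucleotides, and Uhrf1 (4.31 ± 0.71). The comparison held 5609 changed genes, 3170 up and 2439 down, 1044 of them by at least 2-fold. For mitosis, 27 of 29 rose, 0 fell and 2 did not pass (27 and 1 adjusted over the list alone, adjusted p = 1.3e-23, or 0.89 with an estimated correlation). For DNA replication and G1/S, 28 of 31 rose, 0 fell and 3 did not pass (28 and 0 adjusted over the list alone, adjusted p = 2.4e-17, or 0.89 with an estimated correlation). In fatty acid synthesis, 0 of 19 rose, 5 fell and 14 did not pass (0 and 5 adjusted over the list alone, adjusted p = 0.0085, or 0.96 with an estimated correlation), with Pklr (-2.02 ± 0.38) and Mlxipl (-1.34 ± 0.35) down. Of the male-biased liver genes, 0 of 14 rose, 4 fell and 10 did not pass (0 and 4 adjusted over the list alone, adjusted p = 0.018, or 0.96 with an estimated correlation), with Hsd3b5 (-4.70 ± 1.25) and Serpina12 (-4.05 ± 0.50) down. At 48 hours the list test also called upward acute phase proteins (15 up and 1 down of 24, 17 and 1 alone) and ribosome biogenesis (15 up and 1 down of 24, 16 and 1 alone), at adjusted p = 3.2e-08 to 4.1e-05, or 0.89 with an estimated correlation. Falls in male-biased liver genes numbered 9 without the doubted arrays and 8 without the arrays with Xist signal. Rises in ribosome biogenesis genes numbered 9 without 48-hour replicate 4. Of the genes changed 56.5% rose, 73.3% after median centring and 45.5% after quantile normalization. A fit with the hybridization controls as a covariate gave 2150 genes.

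At 3 days mitosis genes were high, and collagens and macrophage genes were higher than in untreated liver. Ccnb2 (5.61 ± 0.72), a mitotic cyclin, was at 8.72 ± 1.95 (SD, n = 4) against 3.11 ± 0.42 (SD, n = 5) in the controls. Col5a2 (2.72 ± 0.38), Col3a1 (2.17 ± 0.50) and Col1a2 (2.09 ± 0.42), chains of fibrillar collagens, rose, as did Timp1 (1.88 ± 0.48), an inhibitor of matrix proteases. Lyve1 (2.70 ± 0.61), a hyaluronan receptor of endothelium, rose. Hsd3b5 (-6.50 ± 1.25) was at least 90.3-fold lower. Differences were called for 7168 genes, 3951 up and 3217 down, and 1522 reached 2-fold. For mitosis, 27 of 29 rose, 1 fell and 1 did not pass (27 and 2 adjusted over the list alone, adjusted p = 1.6e-15, or 0.89 with an estimated correlation). Birc5 (5.38 ± 0.72) and Ube2c (5.26 ± 0.71) rose, whereas Foxm1 (-0.55 ± 0.15), a transcription factor of the mitotic genes, fell. Replicate 2 of the group had Mki67 at 5.12, and the other 3 arrays lay between 8.87 and 9.42. For extracellular matrix and myofibroblast genes, 15 of 22 rose, 0 fell and 7 did not pass (16 and 0 adjusted over the list alone, adjusted p = 4.2e-05, or 0.89 with an estimated correlation). Of the Kupffer cell markers, 11 of 15 rose, 0 fell and 4 did not pass (12 and 0 adjusted over the list alone, adjusted p = 0.00088, or 0.89 with an estimated correlation), with Vsig4 (2.65 ± 0.54) and Marco (2.42 ± 0.53) up. The hybridization controls of the 3-day arrays averaged 9.73 ± 0.32 (SD, n = 4). Fetal liver and progenitor genes did not pass as a list in the main fit, and 9 of 19 rose, 0 fell and 10 did not pass (9 and 0 adjusted over the list alone, adjusted p = 0.051, or 0.89 with an estimated correlation), with Afp (3.61 ± 0.48), Scd2 (2.60 ± 0.47) and Tff3 (2.49 ± 0.50) up. At 3 days the list test also called upward acute phase proteins (17 up and 1 down of 24, 17 and 1 alone) and p53 targets (8 up and 2 down of 16, 10 and 2 alone), at adjusted p = 1.1e-06 to 0.022, or 0.89 with an estimated correlation. The call of p53 targets ended under at least 1 alternative. Rises in Kupffer cell markers numbered 7 without 3-day replicates 1 or 4. The share of called genes that rose was 55.1%, 69.9% after median centring and 44.9% after quantile normalization, and centring moved the median of all genes from -0.015 to 0.097. With the hybridization controls as a covariate, 188 genes passed, and of the genes named here calls remained for Lyve1 and Hsd3b5 alone, and 3007 passed with the poly-A controls. The 13 named calls ended by the hybridization covariate kept 47.5% (Scd2, 1.23 ± 0.72) to 116% of their change (median 72.7%), with 1.6 times the error. Calls ended for Foxm1 (-0.006) with the mean of the probe sets and for Timp1 and Hsd3b5 (-3.69) with the poly-A controls. More genes fell than rose with the hybridization covariate (77 up and 111 down).

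At 4 days collagen, macrophage and mitosis genes and 10 of 19 fetal liver genes were higher than in the controls. Scd2 (3.82 ± 0.47), a desaturase, Afp (3.39 ± 0.48) and Lpl (2.94 ± 0.48), lipoprotein lipase, rose. Col5a2 (2.75 ± 0.38) and Col4a1 (2.37 ± 0.29) rose among the collagens, and Marco (3.36 ± 0.53) among the macrophage genes. Prtn3 (4.71 ± 0.63), a protease of myeloid granules, was among the highest at 8.99 ± 0.65 (SD, n = 4) against 4.28 ± 0.32 (SD, n = 5) in the controls. Of all genes 5974 changed, 3414 up and 2560 down, 1097 of them by at least 2-fold. For extracellular matrix and myofibroblast genes, 16 of 22 rose, 0 fell and 6 did not pass (16 and 0 adjusted over the list alone, adjusted p = 9.9e-08, or 0.89 with an estimated correlation), with Col1a2 (2.28 ± 0.42) and Col3a1 (2.19 ± 0.50) up. Among Kupffer cell markers, 10 of 15 rose, 0 fell and 5 did not pass (12 and 0 adjusted over the list alone, adjusted p = 3.3e-05, or 0.89 with an estimated correlation), with C1qb (2.45 ± 0.49) and Vsig4 (2.38 ± 0.54) up. The hybridization controls averaged 9.86 ± 0.11 (SD, n = 4) at this time. For mitosis, 24 of 29 rose, 2 fell and 3 did not pass (26 and 2 adjusted over the list alone, adjusted p = 4.4e-08, or 0.89 with an estimated correlation). Ccnb2 (4.19 ± 0.72) and Mki67 (3.90 ± 0.76) rose. At 4 days the list test also called upward acute phase proteins (18 up and 0 down of 24, 19 and 1 alone) and fetal liver and progenitor genes (10 up and 1 down of 19, 10 and 1 alone), at adjusted p = 4.4e-08 to 0.0048, or 0.89 with an estimated correlation. The call of fetal liver and progenitor genes ended under at least 1 alternative. Rises in fetal liver and progenitor genes numbered 5 without 4-day replicate 2. Of the genes changed 57.1% rose, 74.1% after median centring and 45.3% after quantile normalization, and centring moved the median of all genes from -0.005 to 0.106. A fit with the hybridization controls as a covariate gave 123 genes, and of the genes named here calls remained for Scd2, Col4a1, Marco and Prtn3 alone, and 1078 passed with the poly-A controls. Calls that the hybridization covariate ended, 9 here, kept 51.5% (Mki67, 2.01 ± 1.08) to 99.7% of their change (median 75.9%), with 1.48 times the error.

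At 1 week male-biased genes were lower than in the controls, and macrophage and collagen genes were higher. Hsd3b5 (-6.92 ± 1.25) was at least 121-fold lower, and Slco1a1 (-4.14 ± 0.74), an organic anion transporter, 17.6-fold lower. Elovl3 (-4.27 ± 0.96), which elongates fatty acids, and Cyp4a12a (-3.98 ± 1.15), a hydroxylase of male liver, fell as well. Marco (3.93 ± 0.53) rose to 7.93 ± 1.40 (SD, n = 4) against 4.00 ± 0.33 (SD, n = 5) in the controls. Col5a2 (2.42 ± 0.38) and Col4a1 (2.01 ± 0.29) were up, and Mki67 (2.75 ± 0.76) was still above the controls. The comparison gave 6683 genes, 3965 up and 2718 down, 1356 of them by at least 2-fold. Among male-biased liver genes, 0 of 14 rose, 10 fell and 4 did not pass (0 and 12 adjusted over the list alone, adjusted p = 6.5e-06, or 0.89 with an estimated correlation). For Kupffer cell markers, 13 of 15 rose, 0 fell and 2 did not pass (13 and 0 adjusted over the list alone, adjusted p = 6.9e-06, or 0.89 with an estimated correlation), with Vsig4 (3.11 ± 0.54) and Cd163 (2.53 ± 0.48) up. The hybridization controls averaged 9.85 ± 0.15 (SD, n = 4). In extracellular matrix and myofibroblast genes, 12 of 22 rose, 0 fell and 10 did not pass (12 and 0 adjusted over the list alone, adjusted p = 0.00012, or 0.89 with an estimated correlation). Of the acute phase proteins, 18 of 24 rose, 0 fell and 6 did not pass (19 and 0 adjusted over the list alone, adjusted p = 9.5e-07, or 0.89 with an estimated correlation). Replicate 4, one of the doubted arrays, had Saa1 at 13.92 and Lcn2 at 12.02. Replicate 4 had Mki67 at 4.13 and Ccnd1 at 4.79, with Ccnd1 between 10.00 and 10.46 in the other 3 arrays. At 1 week the list test also called upward ribosome biogenesis (17 up and 0 down of 24, 19 and 1 alone), at adjusted p = 0.00038, or 0.89 with an estimated correlation. Rises in acute phase proteins numbered 11 without the doubted arrays. Rises in ribosome biogenesis genes numbered 10 without the doubted arrays. The share of called genes that rose was 59.3%, 75.6% after median centring and 45.9% after quantile normalization, and centring moved the median of all genes from 0.021 to 0.148. With the hybridization controls as a covariate, 141 genes passed, and of the genes named here calls remained for Hsd3b5, Slco1a1, Marco and Col4a1 alone, and 3613 passed with the poly-A controls. The 6 named calls ended by the hybridization covariate kept 29.8% (Mki67, 0.82 ± 1.09) to 113% of their change (median 82.9%), with 1.51 times the error. Without the doubted arrays Cd163 stood at 1.58. Calls ended for Cyp4a12a (-2.43) with the poly-A controls and for Cyp4a12a (-2.51) with the Gapdh difference.

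At 2 weeks, where 2 arrays were measured, macrophage markers were higher than in untreated liver. Vsig4 (3.14 ± 0.67) and C1qb (3.32 ± 0.61) were at least 8.85-fold and at least 10-fold above the controls. The metallothioneins Mt2 (5.11 ± 0.62) and Mt1 (4.48 ± 0.55) and Coq10b (2.77 ± 0.41), a protein of coenzyme Q handling, rose. The test called 620 genes, 510 up and 110 down, 284 of them by at least 2-fold. Of the Kupffer cell markers, 10 of 15 rose, 0 fell and 5 did not pass (13 and 0 adjusted over the list alone, adjusted p = 8.6e-14, or 0.89 with an estimated correlation). The hybridization controls averaged 9.89 ± 0.06 (SD, n = 2). Rises in Kupffer cell markers numbered 4 without control replicate 1 and 0 without 2-week replicates 1 or 2. Of the genes changed 82.3% rose, 90.8% after median centring and 52.8% after quantile normalization. A fit with the hybridization controls as a covariate gave 5 genes, and of the genes named here calls remained for Mt2 and Mt1 alone, 172 passed with the poly-A controls and 330 with the Gapdh difference, and 15 without replicate 1, 57 without replicate 2 and 201 without control replicate 1. Calls that the hybridization covariate ended, 4 with Per1 of the closing section, kept 60.1% (Coq10b, 1.67 ± 0.49) to 99.5% of their change (median 75.9%), with 1.31 times the error. Without 2-week replicate 1 the calls of Vsig4 (2.98) and C1qb (3.40) ended. Without 2-week replicate 2 the calls of Vsig4 (3.31) and C1qb (3.25) ended.

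At 4 weeks macrophage markers and metallothioneins were higher than in the controls, and the immediate early genes Dusp1 and Ier2 were lower. C1qb (2.36 ± 0.49) and Vsig4 (2.41 ± 0.54) rose, as did Mt2 (4.91 ± 0.50) and Mt1 (4.28 ± 0.44). Slc16a5 (2.05 ± 0.34), a monocarboxylate transporter, was among the highest. Dusp1 (-2.02 ± 0.37) and Ier2 (-1.63 ± 0.30) fell, and Angptl8 (-2.92 ± 0.67), a regulator of lipid storage, was 7.58-fold lower. Changed genes at this time were 2677, 1697 up and 980 down, 405 of them by at least 2-fold. Of the Kupffer cell markers, 8 of 15 rose, 0 fell and 7 did not pass (12 and 0 adjusted over the list alone, adjusted p = 3.4e-07, or 0.89 with an estimated correlation). The hybridization controls averaged 10.17 ± 0.07 (SD, n = 4). Among acute phase proteins, 9 of 24 rose, 0 fell and 15 did not pass (13 and 0 adjusted over the list alone, adjusted p = 1.3e-07, or 0.89 with an estimated correlation). Replicate 1, one of the doubted arrays, had Lcn2 at 12.75, and the other 3 had it between 4.97 and 9.09. Of the proteasome subunits, 12 of 25 rose, 1 fell and 12 did not pass (15 and 1 adjusted over the list alone, adjusted p = 2e-07, or 0.89 with an estimated correlation). Psma1 (0.91 ± 0.16) and Psmc1 (0.85 ± 0.17) rose, and Psmb3 (-0.67 ± 0.14) fell. Hadhb (1.06 ± 0.19), of fatty acid oxidation, and Angptl4 (1.81 ± 0.41) rose. Rises in Kupffer cell markers numbered 5 without control replicate 1 and 4 without 4-week replicate 4. Rises in acute phase proteins numbered 2 without 4-week replicate 1 or the doubted arrays. Rises in proteasome subunits numbered 7 without 4-week replicate 1 and 6 without control replicate 1 or the doubted arrays. The share of called genes that rose was 63.4%, 81.5% after median centring and 49.5% after quantile normalization. With the hybridization controls as a covariate, 223 genes passed, and of the genes named here calls remained for C1qb, Mt2, Mt1, Dusp1 and Ier2 alone, 769 passed with the poly-A controls, 1076 with the Gapdh difference, 1421 without replicate 1 and 1251 without control replicate 1. The 8 named calls ended by the hybridization covariate kept 49.3% (Psmc1, 0.42 ± 0.19) to 108% of their change (median 70%), with 1.21 times the error. Without the doubted arrays Angptl4 stood at 1.16, Hadhb at 0.61 and Psmc1 at 0.56. Calls ended for Psma1 (0.13) with the mean of the probe sets, for Angptl4 without the doubted arrays, for Angptl8 and Angptl4 (1.14) with the poly-A controls, for Psmc1 (0.56) and Psmb3 (-0.40) with the Gapdh difference and for Psmc1 and Hadhb in a fit of these groups alone. More genes fell than rose with the hybridization covariate (94 up and 129 down).

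At 3 months macrophage genes were still above the untreated controls. Vsig4 (3.44 ± 0.58) reached 7.86 ± 1.13 (SD, n = 3) against 4.42 ± 0.55 (SD, n = 5) in the controls. Marco (2.71 ± 0.58), Cd5l (2.50 ± 0.51), which macrophages secrete, and Cd163 (2.48 ± 0.52), the haemoglobin scavenger receptor, rose, together with Lyz1 (3.23 ± 0.59) and Lyz2 (2.90 ± 0.55). Scara5 (3.00 ± 0.71), a ferritin receptor, and the metallothioneins Mt1 (4.10 ± 0.48) and Mt2 (4.09 ± 0.54) rose. Genes changed numbered 5476, 3034 up and 2442 down, 788 of them by at least 2-fold. Of the Kupffer cell markers, 13 of 15 rose, 0 fell and 2 did not pass (15 and 0 adjusted over the list alone, adjusted p = 2.3e-08, or 0.89 with an estimated correlation). The hybridization controls averaged 9.85 ± 0.34 (SD, n = 3). Of the fatty acid oxidation and PPARa targets, 11 of 24 rose, 1 fell and 12 did not pass (11 and 1 adjusted over the list alone, adjusted p = 0.0025, or 0.89 with an estimated correlation). Cyp4a14 (2.79 ± 0.85), Cd36 (1.84 ± 0.37) and Hadhb (1.34 ± 0.21) rose, and Crat (-1.25 ± 0.25), an acyl transferase, fell. The call of fatty acid oxidation and PPARa targets ended under at least 1 alternative. Of the genes changed 55.4% rose, 69.8% after median centring and 47.5% after quantile normalization, and centring moved the median of all genes from 0.010 to 0.113. With the hybridization controls as a covariate limma called 0 genes, and 2208 had an unadjusted p under 0.05, while 2209 passed with the poly-A controls and 3481 without replicate 1. Calls that the hybridization covariate ended, 13 here, kept 43.1% (Crat, -0.54 ± 0.33) to 113% of their change (median 84.8%), with 1.44 times the error. Calls ended for Crat (-0.20) with the mean of the probe sets.

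**Figure D2:**
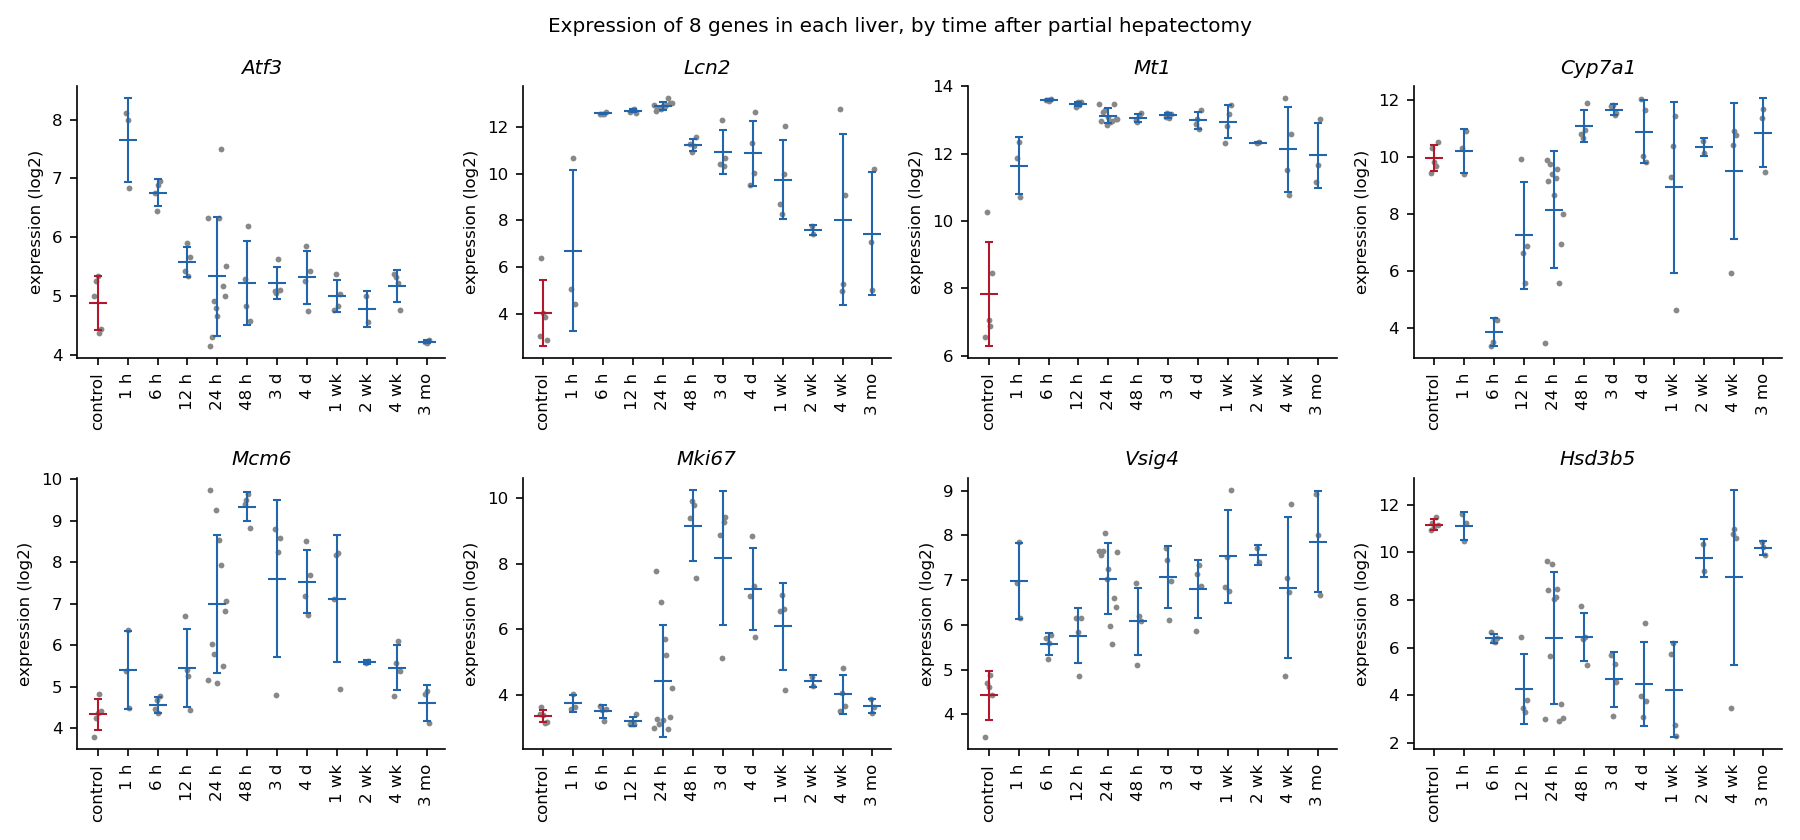
Log2 expression of Atf3, Lcn2, Mt1, Cyp7a1, Mcm6, Mki67, Vsig4 and Hsd3b5 on each of the 52 arrays (points) with group means and SD, in the controls and the 11 times after partial hepatectomy. Mki67 averaged 9.17 at 48 hours and 3.34 in the controls.

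**Figure D3:**
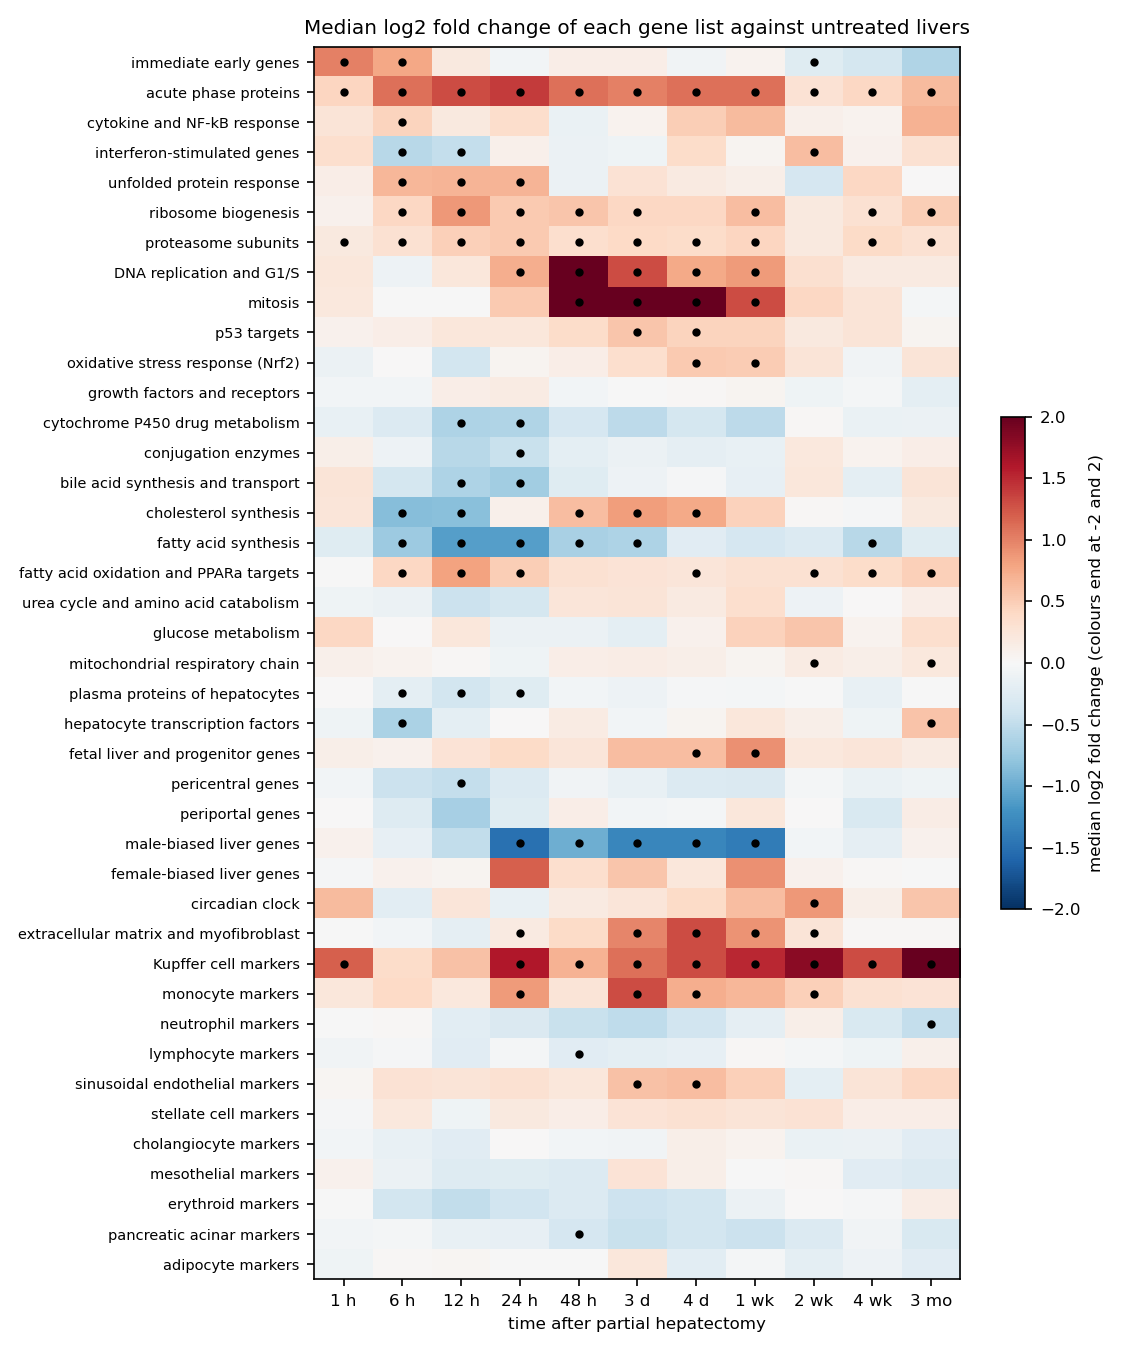
Median log2 fold change of the measured members of the 41 fixed gene lists at each of the 11 times against the controls, with points on the calls of the list test and a colour scale that ends at -2 and 2. The mitosis list had a median of 3.9 at 48 hours.

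The contrasts between times do not compare with the control arrays, which enter only the estimate of the spread. Between 1 and 6 hours, 11 of 24 acute phase genes rose, and 9 of 19 genes of cholesterol synthesis fell. Lcn2 (5.86 ± 1.16) and Steap4 (3.31 ± 0.52), a metalloreductase, rose. Cyp7a1 (-6.35 ± 1.19) fell at least 81.4-fold, to 3.87 ± 0.49 (SD, n = 4) against 10.21 ± 0.76 (SD, n = 3) at 1 hour. Cdkn1a (4.91 ± 0.66) rose, and so did Pdk4 (5.17 ± 0.98). This contrast gave 1980 genes, 809 up and 1171 down, 918 of them by at least 2-fold. Of the acute phase proteins, 11 of 24 rose, 0 fell and 13 did not pass (14 and 0 adjusted over the list alone, adjusted p = 1.7e-09, or 0.61 with an estimated correlation). In cholesterol synthesis, 0 of 19 rose, 9 fell and 10 did not pass (0 and 12 adjusted over the list alone, adjusted p = 4.9e-08, or 0.61 with an estimated correlation), with Insig1 (-2.69 ± 0.43) and Fdft1 (-2.21 ± 0.39) down. In fatty acid synthesis, 0 of 19 rose, 4 fell and 15 did not pass (0 and 6 adjusted over the list alone, adjusted p = 0.0013, or 0.73 with an estimated correlation), with Srebf1 (-3.28 ± 0.58) down. In bile acid synthesis and transport, 0 of 21 rose, 5 fell and 16 did not pass (1 and 6 adjusted over the list alone, adjusted p = 0.0014, or 0.61 with an estimated correlation), with Nr0b2 (-3.01 ± 0.72) down. Over this interval the list test also called downward interferon-stimulated genes (0 up and 9 down of 19, 0 and 11 alone), at adjusted p = 9.7e-07, or 0.61 with an estimated correlation. Rises in acute phase proteins numbered 5 without 1-hour replicate 1 and 3 without 1-hour replicate 3. Falls in fatty acid synthesis genes numbered 9 without the doubted arrays. Falls in bile acid synthesis and transport genes numbered 10 without the doubted arrays. Falls in interferon-stimulated genes numbered 5 without 1-hour replicates 1 or 3 or 6-hour replicate 2 and 3 without 1-hour replicate 2. Fitted on these groups alone the count was 4795, without 1-hour replicate 1 it was 1294, and without the doubted arrays, none of them from these times, it was 2994.

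Between 12 and 24 hours, 10 of 19 genes of cholesterol synthesis and 7 of 15 macrophage markers rose. Nsdhl (1.64 ± 0.32), Hmgcs1 (1.44 ± 0.30) and Cyp51 (1.31 ± 0.20) rose among the first. Marco (1.70 ± 0.46) rose, as did Clec4f (1.14 ± 0.29), a lectin of Kupffer cells. Gsta2 (-2.72 ± 0.42), a glutathione transferase, was among the lowest. The count was 1768, 934 up and 834 down, 313 of them by at least 2-fold. For cholesterol synthesis, 10 of 19 rose, 0 fell and 9 did not pass (15 and 0 adjusted over the list alone, adjusted p = 2.9e-11, or 0.42 with an estimated correlation). Among Kupffer cell markers, 7 of 15 rose, 0 fell and 8 did not pass (11 and 0 adjusted over the list alone, adjusted p = 1.2e-06, or 0.61 with an estimated correlation). Rises in cholesterol synthesis genes numbered 16 without the doubted arrays and 6 without 12-hour replicate 4. Rises in Kupffer cell markers numbered 4 without 12-hour replicate 2 and 2 without 12-hour replicate 3. The count was 1174, 1102, 1140 and 1083 without 12-hour replicates 1, 2, 3 and 4, and 3828 with 24-hour replicates 1 to 4 only. Calls ended for Marco with 24-hour replicates 5 and 6 only and for Marco and Clec4f (0.58) with 24-hour replicates 7 to 11 only. More genes fell than rose with the mean of the probe sets (893 up and 902 down), with quantile normalization (1057 and 1190), with array weights (1835 and 2261), with 24-hour replicates 5 and 6 only (326 and 692) and with 24-hour replicates 7 to 11 only (794 and 1255).

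Between 24 and 48 hours mitosis genes rose. Ccnb2 (5.08 ± 0.63) rose to 8.41 ± 1.54 (SD, n = 4) against 3.33 ± 0.90 (SD, n = 11) at 24 hours. Cdc20 (5.03 ± 0.72), Birc5 (4.81 ± 0.62), Mki67 (4.76 ± 0.66) and Ube2c (4.14 ± 0.62) rose with it, and so did Cdca3 (4.07 ± 0.54) and Cdkn3 (3.94 ± 0.48), regulators of mitotic entry. Sdf2l1 (-2.51 ± 0.35), Hyou1 (-1.36 ± 0.23) and Pdia4 (-1.44 ± 0.25), of protein folding in the endoplasmic reticulum, fell. Changed genes numbered 997, 650 up and 347 down, 300 of them by at least 2-fold. The lowest included Nucb2 (-3.04 ± 0.36) and Derl3 (-2.31 ± 0.37), a factor of protein disposal. For mitosis, 27 of 29 rose, 0 fell and 2 did not pass (27 and 0 adjusted over the list alone, adjusted p = 4.1e-58, or 0.033 with an estimated correlation). In DNA replication and G1/S, 22 of 31 rose, 0 fell and 9 did not pass (27 and 0 adjusted over the list alone, adjusted p = 1.4e-25, or 0.27 with an estimated correlation), with Rrm2 (3.03 ± 0.71) and Uhrf1 (2.61 ± 0.61) up. For the unfolded protein response, 0 of 20 rose, 11 fell and 9 did not pass (1 and 14 adjusted over the list alone, adjusted p = 5.4e-12, or 0.27 with an estimated correlation). Falls in unfolded protein response genes numbered 7 without 48-hour replicate 4. The count was 557 without 48-hour replicate 2, 560 without replicate 3, 600 without the 3 arrays with Xist signal, and 3646 with 24-hour replicates 7 to 11 only. Calls ended for Uhrf1 in a fit of these groups alone and for Rrm2 and Uhrf1 with 24-hour replicates 5 and 6 only. More genes fell than rose with 24-hour replicates 1 to 4 only (398 up and 728 down).

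Between 48 hours and 1 week 27 of 29 mitosis genes fell. Prc1 (-2.93 ± 0.51), which bundles microtubules at the end of mitosis, fell at least 7.63-fold. Birc5 (-3.33 ± 0.76) fell as well. Hamp2 (2.39 ± 0.53), Gpcpd1 (1.97 ± 0.39), Defb1 (1.90 ± 0.33), an antimicrobial peptide, and Spink1 (1.81 ± 0.34), a protease inhibitor, rose. Genes past the threshold numbered 558, 256 up and 302 down, 232 of them by at least 2-fold. For mitosis, 0 of 29 rose, 27 fell and 2 did not pass (0 and 28 adjusted over the list alone, adjusted p = 1.6e-39, or 0.15 with an estimated correlation). For DNA replication and G1/S, 0 of 31 rose, 12 fell and 19 did not pass (0 and 27 adjusted over the list alone, adjusted p = 1.3e-23, or 0.27 with an estimated correlation). Falls in mitosis genes numbered 14 without 48-hour replicate 1, 13 without 48-hour replicate 3 or the doubted arrays, 12 without 48-hour replicate 2 and 8 without 1-week replicate 4. Falls in DNA replication and G1/S genes numbered 3 without 48-hour replicates 1 or 2 or the doubted arrays and 2 without 48-hour replicate 3 or 1-week replicate 4. Fitted on these groups alone the count was 9, and it was 195, 172 and 220 without 48-hour replicates 1, 2 and 3, 252 without 1-week replicate 4 and 306 with the poly-A controls as a covariate, and with the hybridization controls 88 genes rose and 494 fell. Without 1-week replicate 4 the call of Birc5 (-2.59) ended. Without 48-hour replicate 2 the call of Birc5 (-3.06) ended. Calls ended for Prc1, Birc5, Hamp2, Gpcpd1 and Defb1 in a fit of these groups alone. More genes rose than fell with array weights (1084 up and 611 down), without the doubted arrays (456 and 253) and with the Gapdh difference (307 and 292).

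Between 1 week and 3 months 5 male-biased genes rose and 3 extracellular matrix genes fell. Slco1a1 (4.49 ± 0.84) rose 22.5-fold, to 10.70 ± 0.06 (SD, n = 3) against 6.20 ± 2.63 (SD, n = 4) at 1 week. Serpina12 (3.64 ± 0.57), an adipokine of liver and fat, and Serpina4-ps1 (5.43 ± 0.66) rose. Col5a2 (-2.53 ± 0.43), Nipal1 (-2.68 ± 0.48) and Spink1 (-2.41 ± 0.37) fell. The number of genes was 147, 55 up and 92 down, 85 of them by at least 2-fold. Of the male-biased liver genes, 5 of 14 rose, 0 fell and 9 did not pass (12 and 0 adjusted over the list alone, adjusted p = 4.3e-17, or 0.15 with an estimated correlation). For extracellular matrix and myofibroblast genes, 0 of 22 rose, 3 fell and 19 did not pass (0 and 16 adjusted over the list alone, adjusted p = 5.1e-13, or 0.27 with an estimated correlation). Among fetal liver and progenitor genes, 0 of 19 rose, 1 fell and 18 did not pass (0 and 7 adjusted over the list alone, adjusted p = 4.6e-06, or 0.031 with an estimated correlation). Rises in male-biased liver genes numbered 11 without the arrays with Xist signal, 10 without the doubted arrays and 2 without 3-month replicates 1, 2 or 3 or 1-week replicates 3 or 4. Falls in extracellular matrix and myofibroblast genes numbered 9 without 1-week replicate 3, 8 without 1-week replicate 1 and 1 without 3-month replicates 1, 2 or 3, 1-week replicate 4 or the doubted arrays. Falls in fetal liver and progenitor genes numbered 5 without the doubted arrays, 2 without the arrays with Xist signal and 0 without 3-month replicates 1 or 3 or 1-week replicate 1. The share of called genes that rose was 37.4%, 34.1% after median centring and 56.5% after quantile normalization. Fitted on these groups alone the count was 6, and it was 87 without 3-month replicate 1, 57 without replicate 3 and 363 without the doubted arrays. Calls ended for Slco1a1, Col5a2 and Nipal1 in a fit of these groups alone. More genes rose than fell in a fit of these groups alone (4 up and 2 down).

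**Figure D4:**
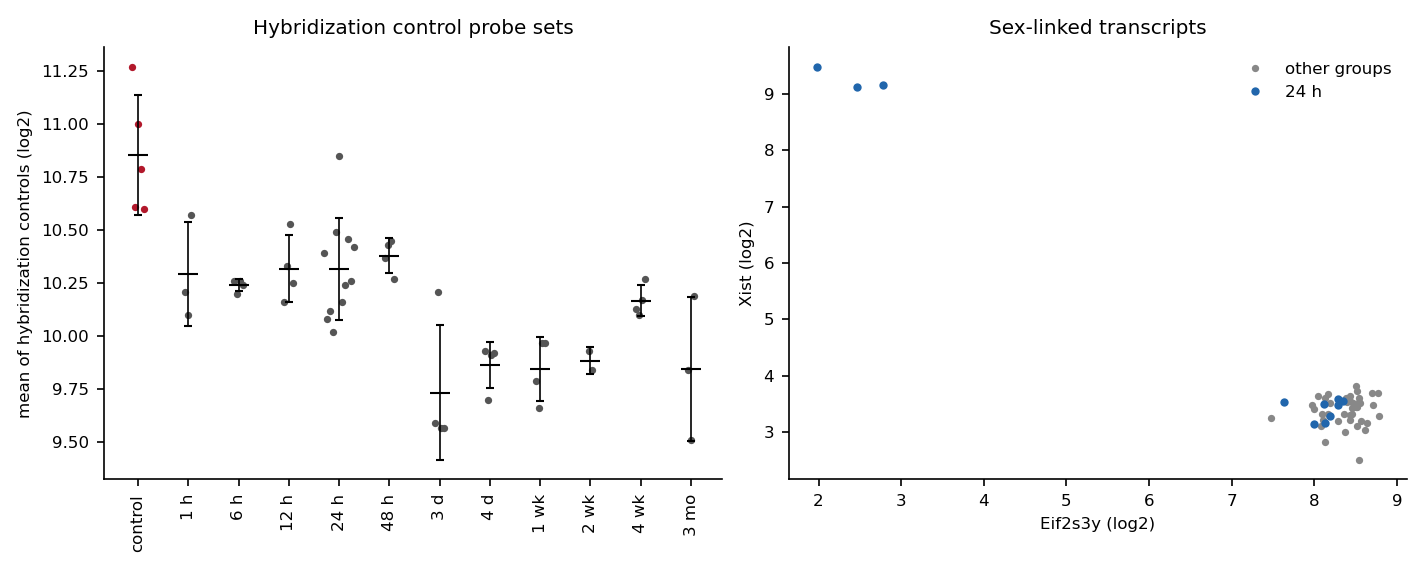
Mean log2 signal of the hybridization controls on each of the 52 arrays by group, with group means and SD (left), and log2 Xist against log2 Eif2s3y, a gene of the Y chromosome, on the same arrays (right). Xist lay between 9.12 and 9.48 in 3 of the 11 arrays of the 24-hour group, and the hybridization controls averaged 10.85 in the controls.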

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

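The tests of explanations in this part were chosen only after the results were seen, and the search for single arrays far from their group used a fixed limit, Dixon's criterion.

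The control arrays stood apart from the 47 others. In 243 genes, Mt1 among them, every control array lay beyond every other array, 35 genes above and 208 below. The median difference was 0.99 (SE 0.13). A labelling batch or RNA quality that its measure tracks would take this difference to near 0. With the poly-A covariate 78.6% was left (0.78, SE 0.15, 239 genes called) and with the Gapdh difference 90% (0.89, SE 0.16, 242 called). Complete separation picked these genes, while both measures overlap between control and other arrays, so a value near 0 was hardly possible. The test therefore cannot decide on a labelling batch or RNA quality. Array hybridization stays open too: with its covariate 63.7% was left (0.63, SE 0.20, 108 called), and its controls were higher in the control group. In the 135 genes whose calls ended the median went from 0.84 (SE 0.13) to 0.46 (SE 0.19), so both a smaller change and a larger error ended them, while 4 of them kept 90% or more of their difference. The operation, which all other arrays share, is a biological explanation that was not tested, and against the controls the Kupffer cell markers had a median of 1.04 and the neutrophil markers of -0.23.

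Of 24-hour arrays labelled male, replicates 9, 10 and 11 had Xist at 9.12 to 9.48, against 2.51 to 3.81 elsewhere. Mixture with male RNA would keep the Y-linked Eif2s3y within about 2 log2 units of other arrays, and it differed by -5.92 (2.41 against 8.33). All 3 Y-linked genes, Eif2s3y, Kdm5d and Uty, lay below every other array, as female livers require, so a candidate explanation is that these samples came from females. Male-biased genes averaged 6.60 to 7.04 in these samples and 8.54 to 10.37 in other 24-hour arrays. Whether labels or animals differ was not tested.

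Replicate 1 of the 4-week group correlated at 0.941 with the 12-hour mean, above the 12-hour arrays themselves, at 0.853 to 0.925 with the rest of their group, and at -0.50 with its own group. Changes in the fixed stress and immune lists alone are argued against, because without these genes the correlation was 0.940 over 1932 genes. A 12-hour sample under another label may therefore account for this array, while the 12-hour arrays all lay with their own group and offer no partner for a swap, which a single wrong label does not need. A late acute response in that animal was not tested. The same array had Cyp7a1 at 5.94, far from the other 3 at 10.43 to 10.92.

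Among 184 sets of arrays, 18 held an array far from the rest of its group, and chance gives about 1 in 20. In the controls Egr1 was 8.77 in replicate 5 against 10.59 to 10.81 in the others, Saa1 was 11.97 in replicate 2 against 7.14 to 8.44, and Afp was 3.94 in replicate 4 against 2.83 to 3.12. In the 12-hour group Mki67 was 3.40 in replicate 4 against 3.12 in the others. In the 48-hour group Hnf4a was 10.98 in replicate 1 against 11.38 to 11.44, and Col1a1 was 6.04 in replicate 3 against 4.80 to 4.93. At 3 days Atf3 was 5.63 in replicate 3 against 5.06 to 5.10. Replicate 2 of that group had Mcm6 at 4.80 against 8.25 to 8.79, Mki67 at 5.12 against 8.87 to 9.42, and hybridization controls at 10.21 against 9.57 to 9.59. At 4 days Myc was 6.02 in replicate 3 against 6.65 to 6.75, and replicate 2 had Glul at 9.91 against 10.83 to 10.90 and hybridization controls at 9.70 against 9.91 to 9.93. Replicate 4 of the 1-week group had Ccnd1 at 4.79 against 10.00 to 10.46, Glul at 9.04 against 10.81 to 10.99, Alb at 13.68 against 14.07 to 14.13 and Hnf4a at 11.94 against 11.12 to 11.23. Over all genes the share with such an array ran from 4.8% at 6 hours to 12.3% at 1 week.

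Of the 19 index genes measured, some passed limma's direct contrast between 2 times and lay on opposite sides of the controls at these times. Cdkn1a stood at 4.90 at 6 hours and -0.01 at 1 hour, a difference of 4.91 (adjusted p = 7.6e-07). Cyp7a1 stood at -6.10 at 6 hours and 0.25 at 1 hour, a difference of -6.35 (adjusted p = 0.00015). Cyp7a1 also stood at 1.12 at 48 hours and -1.81 at 24 hours, a difference of 2.92 (adjusted p = 0.046).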

How the results depend on the processing

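Alternatives added after seeing the data are named in the first part. Of the 198 named changes, 0 reversed under any alternative. All 198 kept their side of the threshold with median centring, a trended and robust prior or quantile normalization. With the mean of probe sets 195 did. Whichever array was left out 192 did, a stability that guided their choice. The hybridization covariate ended 58 of these calls, the poly-A covariate 6, the Gapdh covariate 4, the fit of the 2 groups alone 13 and leaving out the doubted arrays 1. The 58 kept 29.8% to 116% of their change with the hybridization covariate (median 77.3%, 16 of them 90% or more), and their errors were at a median 1.45 times as large. The count of genes changed at any time lay between 8846 and 14825 under the alternatives run for it. Totals of changed genes not given here stayed within 1.5 times the reported value. Counted by direction, 9 of 16 falling counts moved further with median centring, 2 with quantile normalization and 5 without dim genes, and 5 rising and 5 falling counts without the doubted arrays. Of called named changes 37 moved over 1.5 times with the mean of probe sets, 20 with the hybridization covariate and 8 without doubted arrays. Without 1 array, which guided their choice, 0 did. Apart from fewer arrays or a stricter threshold the cause of a change was not tested. Low signal limits dim genes.

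With an adjusted p under 0.01 there were 321 at 1 hour, 3691 at 24 hours, 3202 at 48 hours, 4732 at 3 days, 3468 at 4 days, 4363 at 1 week, 158 at 2 weeks, 1172 at 4 weeks, 3021 at 3 months, 1141 from 1 to 6 hours, 825 from 12 to 24 hours, 463 from 24 to 48 hours, 144 from 48 hours to 1 week and 36 from 1 week to 3 months. Changes of at least 2-fold numbered 198 at 1 hour, 1327 at 6 hours, 1634 at 12 hours, 910 at 24 hours, 1044 at 48 hours, 1522 at 3 days, 1097 at 4 days, 1356 at 1 week, 284 at 2 weeks, 405 at 4 weeks, 788 at 3 months, 918 from 1 to 6 hours, 313 from 12 to 24 hours, 300 from 24 to 48 hours, 232 from 48 hours to 1 week and 85 from 1 week to 3 months. Testing every probe set gave 1656 at 1 hour and 276 from 1 week to 3 months, and array weights gave 2345 at 1 hour, 6688 at 6 hours, 1792 at 2 weeks, 4871 from 1 to 6 hours, 4096 from 12 to 24 hours, 1963 from 24 to 48 hours, 1695 from 48 hours to 1 week and 684 from 1 week to 3 months. The 2 groups alone gave 1533 at 4 weeks, 4795 from 1 to 6 hours, 449 from 24 to 48 hours, 9 from 48 hours to 1 week and 6 from 1 week to 3 months. Of the 24-hour arrays, replicates 1 to 4 gave 3828 from 12 to 24 hours, replicates 5 and 6 gave 773 at 24 hours, 1018 from 12 to 24 hours and 532 from 24 to 48 hours and replicates 7 to 11 gave 3646 from 24 to 48 hours.

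With the hybridization controls as a covariate there were 16 at 1 hour, 2424 at 24 hours, 2150 at 48 hours, 188 at 3 days, 123 at 4 days, 141 at 1 week, 5 at 2 weeks, 223 at 4 weeks and 0 at 3 months. At 3 months the median change of the 5476 genes went from 0.65 (SE 0.18) to 0.36 (SE 0.25), and 94.5% kept their direction. Both a smaller change and a larger error thus ended the calls. The poly-A covariate gave 376 at 1 hour, 3007 at 3 days, 1078 at 4 days, 3613 at 1 week, 172 at 2 weeks, 769 at 4 weeks, 2209 at 3 months, 306 from 48 hours to 1 week and 283 from 1 week to 3 months. The Gapdh covariate gave 237 at 1 hour, 330 at 2 weeks and 1076 at 4 weeks. Without the doubted arrays there were 1065 at 4 weeks, 2994 from 1 to 6 hours, 3240 from 12 to 24 hours and 363 from 1 week to 3 months, and without the 3 arrays with Xist signal 600 from 24 to 48 hours and 236 from 1 week to 3 months.

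Leaving out 1 array at a time moved the count over 269 to 1111 at 1 hour, 3355 to 3958 at 6 hours, 4312 to 5393 at 12 hours, 4260 to 6036 at 24 hours, 4152 to 5549 at 48 hours, 5650 to 7908 at 3 days, 4034 to 5855 at 4 days, 5461 to 6466 at 1 week, 15 to 787 at 2 weeks, 1251 to 2770 at 4 weeks, 3481 to 5397 at 3 months, 1294 to 1637 from 1 to 6 hours, 1083 to 2069 from 12 to 24 hours, 557 to 1306 from 24 to 48 hours, 172 to 765 from 48 hours to 1 week and 57 to 199 from 1 week to 3 months. Where it left 1 array at 2 weeks, that array was taken to vary like the other groups.

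The replicate numbers do not pair the arrays: deviations from the group means correlated at -0.011 between arrays with the same number and 0.007 between others, and 41 of 224 same-number pairs exceeded 0.1, the lowest at -0.55. With the replicate block 3177 genes passed from 12 to 24 hours, the one total it moved by over 1.5 times, and among named changes the call of Slco1a1 at 24 hours ended (-1.42, adjusted p = 0.055). The direction with more genes turned with the block at 6 hours (1997 up and 2050 down), from 24 to 48 hours (283 up and 414 down) and from 48 hours to 1 week (332 up and 325 down).

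Of the list calls, 0 against the controls and 2 between times remained with an estimated correlation, and fry made 21 between times. In the camera test with the preset correlation, 53 calls against the controls and 38 between times held under every other alternative run for lists. Against the controls the filter on dim genes, which tests fewer genes, ended 46, the hybridization covariate 30 and quantile normalization 25, and between times leaving out the doubted arrays ended 23. Leaving out 1 array gave 107 to 126 list calls against controls and 75 to 83 between times. It ended 32 and 29 of the calls at least once, and 52 of the 53 and 38 of the 38 held there too.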

Other observations

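Gene groups not described above also moved at single times. At 2 weeks the circadian clock list was called upward (adjusted p = 0.011, or 0.89 with an estimated correlation). The clock gene Dbp ran from 6.26 to 10.94 in controls, 5.16 to 6.98 at 6 hours and 10.86 to 10.98 at 2 weeks. A time-of-day effect stays open at each time. In the list 4 of 19 rose, 0 fell and 15 did not pass (9 and 2 adjusted over the list alone). Its member Per1 (1.18 ± 0.25) rose, a call that ended in a fit of the 2 groups (1.18), with the hybridization (0.85) or poly-A controls (0.90) and without 2-week replicate 1 (1.05) or 2 (1.31). Rises in circadian clock genes numbered 7 without control replicate 5, 2 without control replicate 2, 1 without control replicate 1 and 0 without 2-week replicates 1 or 2. Between 48 hours and 1 week glucose metabolism was called upward, and 2 of 12 rose, 0 fell and 10 did not pass (2 and 0 adjusted over the list alone, adjusted p = 0.0088, or 0.61 with an estimated correlation). Rises in glucose metabolism genes numbered 7 without the doubted arrays, 1 without 48-hour replicate 3 or 1-week replicates 1 or 2 and 0 without 48-hour replicates 1 or 2. Its call ended without 1-week replicate 2 (adjusted p = 0.054), with adjusted p from 1e-08 to 0.27 over alternatives at the preset correlation.

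Pancreatic acinar markers, genes of the exocrine pancreas, were called downward at 48 hours, and 0 of 9 rose, 4 fell and 5 did not pass (0 and 4 adjusted over the list alone, adjusted p = 0.042, or 0.89 with an estimated correlation). Falls in pancreatic acinar markers numbered 1 without 48-hour replicate 3. The acinar call ended without 48-hour replicates 3 or 4 (adjusted p = 0.077 and 0.06) or control replicates 4 or 5 (0.05, 0.059). Over alternatives at the preset correlation adjusted p ran from 0.022 to 0.089. Cela1 (-0.88 ± 0.25), an elastase, fell. Each of these 3 list calls ended under at least 1 alternative.

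In the main fit the camera test was in no comparison past the threshold for growth factors and receptors, female-biased liver genes, stellate cell markers, cholangiocyte markers or erythroid markers. Its lowest adjusted p was 0.072 for growth factors and receptors, between 24 and 48 hours, and 0.057 for stellate cell markers, between 12 and 24 hours. Between 1 week and 3 months it was 0.095 for cholangiocyte markers and 0.061 for erythroid markers, whose test and mean (0.46) were upward while their median was -0.032. Female-biased genes came closest at 24 hours, where 4 of 13 rose, 0 fell and 9 did not pass (4 and 0 adjusted over the list alone, adjusted p = 0.05, or 0.89 with an estimated correlation), with Cyp4a14 (3.32 ± 0.63) up, in a group that holds the 3 arrays with Xist signal. Single alternatives did call these lists, with adjusted p as low as 0.023 for growth factors and receptors from 24 to 48 hours, 0.0081 for stellate cell markers at 4 days, 0.0098 for cholangiocyte and 0.015 for erythroid markers from 1 week to 3 months, and 0.00015 for female-biased genes at 24 hours with replicates 7 to 11 only, which hold the 3 Xist arrays.

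Other splits of the same arrays into groups of the same sizes were fitted for each count of genes, a test chosen only after the counts were seen. Of 100 splits the real one gave most genes at 6 hours (3999, highest other 3004), 12 hours (5445, 4145) and 24 hours (5776, 2249). So it did at 48 hours (5609, 4198), 3 days (7168, 5517), 4 days (5974, 4227), 1 week (6683, 4983) and 4 weeks (2677, 1983). It did too among 56 splits at 3 months (5476, 2549). Among 35 it did between 1 and 6 hours (1980, 593) and between 48 hours and 1 week (558, 298). As many genes came from 2 of 56 splits at 1 hour (917, highest other 1014). Between 12 and 24 hours 2 of 100 did (1768, highest other 2043). These tests were not corrected for their number, so few such splits make chance less likely and do not exclude it. Chance stays open between 24 and 48 hours, where 6 of 100 splits gave as many (997, highest other 3721). It does between 1 week and 3 months, where 4 of 35 did (147, highest other 280). Between 24 and 48 hours the highest split set 24-hour replicates 2, 3 and 4 and 48-hour replicate 3 against the rest. This points to a structure among these arrays. No splits were fitted for 2 weeks, which has 2 arrays.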
